A study of Mus musculus with 12 samples.

How the data were processed

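The series covers 12 samples of mouse small pre-B cells, sorted from bone marrow, in 6 groups of 2 biological replicates per the labels: ChIP-seq with antibodies to BRWD1, H3K9Ac and H3S10pK14Ac, input DNA, and ATAC-seq of wild-type and Brwd1 mutant cells. The 6 ChIP-seq peak lists were analysed. The 2 input and 4 ATAC-seq samples, and the RNA-seq that the series' design text mentions, are not analysed here. Samples were grouped by their titles and descriptions, and replicate numbers were taken from the same labels. The descriptions of the Brwd1 mutant ATAC-seq samples name pro-B cells, whereas their source label names small pre-B cells.

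Per the submitters' processing notes, the tools were Trimmomatic 0.32, BWA 0.7.5, Picard and MACS2, and the genome build was mm9. The notes name tools without their roles or order; read trimming, alignment, duplicate handling and peak calling are their usual uses. The settings, the input library each ChIP-seq library was compared with, and the treatment of multiply mapped reads are not given in the sources used here. The names of the 6 lists join the replicate number to a further number, which is 2 in each; it might stand for a common input library, but its meaning is not given in the sources used here. The authors deposited a peak list for each replicate library, not a list from pooled replicates. Each list has 5 columns and no header: chromosome, start, end, peak name and score. The deposited score is the authors' −log10 of the significance of a peak; whether this is a p-value or a q-value is not given in the sources used here. This unit was read from the naming of the lists and from the values, none of which lies below 5. The numbers in the peak names ran to between 14528 and 145512, past the length of each list, so each list is a part of a longer one. A single score value was shared by 18.4 to 43.4% of the peaks of a list, which limits ranking among the weakest peaks. Peak widths also differed between lists: the median was 71.5 and 196 bp for BRWD1, 375 and 208 bp for H3K9Ac, and 63 and 175 bp for H3S10pK14Ac in replicates 1 and 2. The lists covered 467 and 2109 kb, 4690 and 4307 kb, and 8.95 and 2054 kb in the same order. Read depth is unknown, so the precision of a peak's score could not be given. Intervals of shares are 95% Wilson intervals and cover counting error of peaks only.

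Peaks on chromosomes 1 to 19, X and Y were used, and coordinates are printed with a first base of 1. Peaks were shared if they overlapped by at least 1 bp. Each list was compared with each other list in both directions, since a share depends on the list that serves as denominator. Chance was the mean overlap after 1000 circular shifts of one of the lists within each chromosome, over the span the peaks cover. For the alternatives to the overlaps between antibodies, listed below, chance came from 200 shifts or placements. The one-sided permutation p counts the shifts with at least the observed overlap, and Benjamini-Hochberg adjustment over the 30 directed pairs left all at 0.001. The shifts ignored mappability, so chance may be understated. These p-values measure the placement of peaks within these libraries, not the spread between replicates, and peaks are not independent replicates. With 2 lists per antibody, an exact two-sided test across replicates cannot go below p = 0.333. Means over combinations of replicate lists are therefore given with their range. H3K9Ac peaks with and without H3S10pK14Ac were compared by a two-sided Fisher's exact test with the peak as unit in each of 8 combinations of 3 lists; odds ratios were computed with 0.5 added to each cell. BRWD1 score ranks were compared between classes by a two-sided permutation test with 100000 resamples. Windows at antigen receptor loci were set in whole megabases of mm9 from general knowledge and include flanking sequence; the percentiles of these windows among all other windows of the same width are descriptions without a test.

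The groups, tests, alternatives and the rule for naming regions were fixed before the data were examined. The rule named the 10 BRWD1 regions with the best mean score rank among those in both replicates, every BRWD1 region of both replicates in the Igk window, the 10 best H3S10pK14Ac replicate 1 peaks, the 5 densest 1 Mb windows of BRWD1 peaks, and 6 antigen receptor windows with their best peaks. The further BRWD1 replicate 2 peak in the Igk window, the Igh region with peaks of all lists and the split of H3S10pK14Ac peaks by H3K9Ac were chosen after the values were seen. The planned comparison of gene promoters needs an mm9 annotation, which was not used here, so no peak was assigned to a gene. The alternatives tried were a 50% overlap of the shorter peak, a distance of 1 kb, scores above the list's median, all sequence names, leaving out the 1% highest scores, equal numbers of top-scored peaks, same-numbered replicates only, unions and intersections of replicates, uniform placement for chance, strata of H3K9Ac peak width and score, and leaving out each replicate. Scores of 10 or more, leaving out regions with a peak in all 5 larger lists, and leaving out the Igk window were added after the data were seen.

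Analyses used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9, with a fixed random seed. Overlap counts were checked against bedtools 2.31.1 for the 30 directed pairs, of which 0 differed. The overlap test was tested on simulated data for the comparison of the 16453 H3K9Ac replicate 2 peaks with BRWD1 replicate 2. With 5% of peaks planted as shared it recovered 4.99 percentage points and passed 0.05 in 20 of 20 simulations, and with 0 planted it passed in 1 of 20. Apart from the planted peaks, both simulated lists were placed uniformly at random on each chromosome, whereas the real peaks were clustered. The simulations therefore checked the code and do not give the false-positive rate of the test on these lists.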

Results

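The data were peak lists from chromatin immunoprecipitation followed by sequencing (ChIP-seq) of mouse small pre-B cells. These bone marrow cells have finished rearranging the immunoglobulin heavy chain locus and rearrange the kappa light chain locus, Igk. Antibodies were directed against BRWD1, a bromodomain and WD repeat protein that reads acetylated histones, against histone H3 acetylated at lysine 9 (H3K9Ac), and against histone H3 that is phosphorylated at serine 10 and acetylated at lysine 14 (H3S10pK14Ac). Each antibody had 2 biological replicates, and each replicate had its own peak list, which gave 6 lists. On the assembled chromosomes the BRWD1 lists held 5814 and 9966 peaks (replicates 1 and 2), the H3K9Ac lists 10118 and 16453, and the H3S10pK14Ac lists 103 and 10638. The read depth of the libraries is unknown, because the lists give no counts. The series title names BRWD1 and recombination at Igk, so the comparisons asked where BRWD1 peaks lay relative to the 2 histone marks and to Igk.

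The strongest BRWD1 peaks were found in both replicates, whereas most weaker ones were found in a single replicate. Of the 5814 BRWD1 peaks of replicate 1, 685 overlapped a peak of replicate 2 (11.8%, 95% Wilson interval 10.98 to 12.6), against 0.114% by chance. The share was 6.13% among BRWD1 replicate 1 peaks scored under 10, 79.3% among the 449 scored 10 or more, and 95.2% among the 165 scored 20 or more. BRWD1 replicate 2 showed 3.94%, 71.9% and 96.2% in the same score bands. H3K9Ac peaks were shared more widely, with 4367 of the 10118 peaks of replicate 1 (43.2%, 42.2 to 44.1) overlapping replicate 2. For H3S10pK14Ac, 31 of the 103 peaks of replicate 1 overlapped replicate 2 (30.1%, 22.1 to 39.5), and only 0.301% of the replicate 2 peaks overlapped replicate 1. With equal numbers of top-scored peaks in these lists the share was 18.4% (12.1 to 27.0). The overlaps of whole lists exceeded every one of 1000 circular shifts (permutation p = 0.001, the smallest these shifts can give); the shares by score were not tested. The score is the authors' peak significance on a −log10 scale, and it was used here only to rank or filter peaks within a list.

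**Figure D1:**
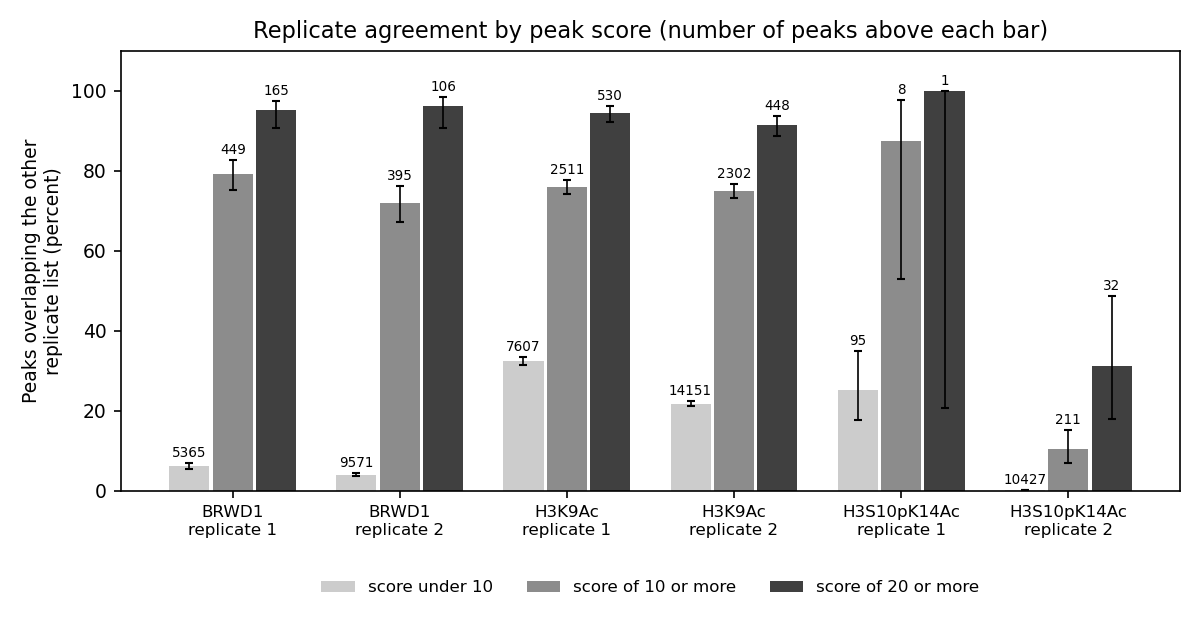
Share of peaks in each list (vertical axis, percent) that overlapped the other replicate of the same antibody by at least 1 bp, for peaks scored under 10, 10 or more and 20 or more, with 95% Wilson intervals and the number of peaks above each bar. In BRWD1 replicate 1 the share was 6.13% for scores under 10 and 95.2% for scores of 20 or more.

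BRWD1 peaks coincided with H3K9Ac, a mark of active promoters and enhancers, many times more often than chance, but in each list most BRWD1 peaks had no H3K9Ac peak. In BRWD1 replicate 1, 667 peaks (11.5%, 10.7 to 12.3) overlapped H3K9Ac replicate 1 and 376 (6.47%, 5.86 to 7.13) overlapped H3K9Ac replicate 2. In BRWD1 replicate 2 the numbers were 869 (8.72%, 8.18 to 9.29) and 962 (9.65%, 9.09 to 10.2). The mean over the 4 combinations was 9.08%, which was 35.4 times the 0.256% expected by chance, and the combinations ranged from 29.0-fold to 52.8-fold. In the other direction, a mean of 5.66% of H3K9Ac peaks overlapped BRWD1 (2.15 to 8.37%, 33.9 times chance). Both means exceeded all 1000 circular shifts (permutation p = 0.001). When the BRWD1 and H3K9Ac lists were filtered alike, the share of BRWD1 peaks with H3K9Ac was 18.4% for scores above the median of each list, 34.5% for scores of 10 or more and 31.6% for peaks found in both replicates of their antibody. Of the BRWD1 peaks that did not overlap H3K9Ac replicate 1, 7.23% and 9.33% (BRWD1 replicates 1 and 2) lay within 10 kb of it, where shifted lists gave 5.98% and 6.07% of all BRWD1 peaks. For H3K9Ac replicate 2 the shares were 12.5% and 13.9%, where shifts gave 10.1% and 10.3%, and these differences were not tested.

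BRWD1 peaks also coincided with the doubly modified histone H3S10pK14Ac. With H3S10pK14Ac replicate 2, 299 peaks of BRWD1 replicate 1 overlapped (5.14%, 4.60 to 5.74, 45.0 times chance) and 546 of BRWD1 replicate 2 (5.48%, 5.05 to 5.94, 32.3 times chance). The short list of H3S10pK14Ac replicate 1 overlapped 0.636% and 0.331% of the BRWD1 peaks. Seen from the mark, 35.9% and 32.0% of the 103 replicate 1 peaks carried BRWD1, and 2.71% and 5.18% of the 10638 replicate 2 peaks did. The mean over the 4 combinations was 2.90% of BRWD1 peaks (40.6 times chance) and 18.96% of H3S10pK14Ac peaks (207 times chance), both above all shifts (permutation p = 0.001). Both means depended on the H3S10pK14Ac library: without replicate 1 they were 5.31% and 3.94% (37.6 and 34.2 times chance), and without replicate 2 they were 0.484% and 34.0% (776 and 437.5 times chance). With both antibodies' lists limited to scores of 10 or more they were 13.9% (1.56 to 29.1) and 69.2% (46.4 to 87.5). H3S10pK14Ac replicate 1 had only 8 such peaks. Without the 1% highest-scored peaks they were 1.98% (0.0710 to 4.25) and 6.64% (1.78 to 13.9). Without the regions with a peak in all 5 larger lists they were 1.68% (0.0306 to 4.04) and 4.70% (1.32 to 9.59). With the 5814 top-scored peaks of each of the other lists, 7.70% of BRWD1 peaks had H3K9Ac and 5.50% had H3S10pK14Ac replicate 2, and whether these shares differ was not tested. The 2 marks overlapped each other as well: 3.95% of H3K9Ac replicate 1 and 4.50% of H3K9Ac replicate 2 peaks had an H3S10pK14Ac replicate 2 peak, 14.2 and 22.9 times chance. The mean over all 4 combinations, 2.25%, was 4.23% without H3S10pK14Ac replicate 1 and 0.280% without replicate 2.

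**Figure D2:**
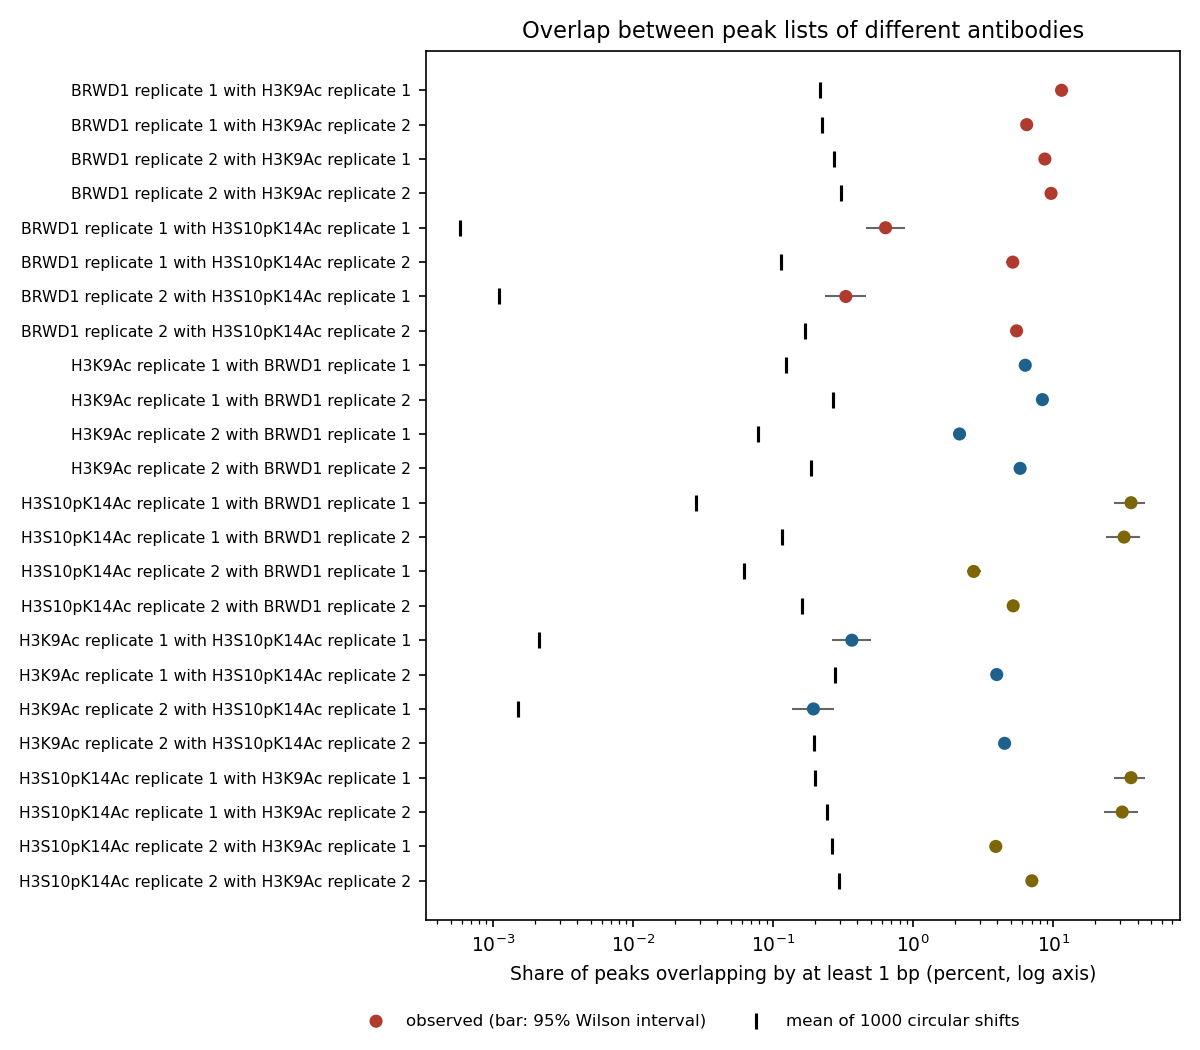
Share of the peaks of the first-named list that overlapped the second-named list by at least 1 bp (horizontal log axis, percent), for each pair of lists of different antibodies; points are observed shares with 95% Wilson intervals, coloured by the first-named antibody, and ticks are the means of 1000 circular shifts. Every point lies above its tick, and the lowest ratio is 14.2 (H3K9Ac replicate 1 with H3S10pK14Ac replicate 2).

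BRWD1 was found far more often at H3K9Ac peaks that also carried H3S10pK14Ac than at H3K9Ac peaks without it. With the larger H3S10pK14Ac list, replicate 2, BRWD1 replicate 1 covered 47.3% of the 400 doubly marked and 4.63% of the 9718 singly marked peaks of H3K9Ac replicate 1. The corresponding shares were 25.8% and 1.03% in H3K9Ac replicate 2, and BRWD1 replicate 2 gave 60% against 6.25% and 40.0% against 4.19%. The odds ratios of these 4 combinations lay between 15.2 and 33.4, with a largest two-sided Fisher's exact p of 1.11e-125. With H3S10pK14Ac replicate 1, which left 32 to 37 doubly marked peaks, 89.2 to 96.9% of these carried BRWD1. The geometric mean odds ratio over the 8 combinations was 78.6 (15.2 to 1048; largest two-sided Fisher's exact p = 7.56e-32). It was 21.4 without H3S10pK14Ac replicate 1, 289 without replicate 2, and 10.2 without the 1% highest-scored peaks of each list. When the regions with a peak in all 5 larger lists were left out, it was 13.9 and the largest p was 0.0963. That setting removes doubly marked peaks with BRWD1 by construction. It left 7 and 2 doubly marked peaks (H3K9Ac replicates 1 and 2) with H3S10pK14Ac replicate 1, and 253 and 591 with H3S10pK14Ac replicate 2.

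The same pattern appeared when these overlaps were counted from the side of the phosphorylated mark. This is a recount with another denominator, chosen after the values were seen, and not separate support. Of the 831 H3S10pK14Ac replicate 2 peaks with H3K9Ac in either replicate, 27.8% (24.9 to 30.9) overlapped BRWD1 replicate 1 and 41.5% (38.2 to 44.9) overlapped BRWD1 replicate 2. Of the 9807 without H3K9Ac, 0.581% (0.449 to 0.752) and 2.10% (1.83 to 2.40) did. These low shares still exceeded chance by 9.62 and 13.3 times (permutation p = 0.001), and the 2 classes differed in both BRWD1 lists (odds ratios 65.4 and 33.0; largest two-sided Fisher's exact p = 2.9e-211). Of the 37 H3S10pK14Ac replicate 1 peaks with H3K9Ac, 35 and 33 overlapped BRWD1 replicates 1 and 2 (94.6% and 89.2%). Most overlaps of H3S10pK14Ac replicate 1 with BRWD1 lay in regions with a peak in all 5 larger lists. Outside them were 7 of 37 with BRWD1 replicate 1 and 3 of 33 with BRWD1 replicate 2. Of the 66 without H3K9Ac, 2 overlapped BRWD1 replicate 1 (3.03%, 0.835 to 10.4; permutation p = 0.002) and 0 overlapped BRWD1 replicate 2 (upper limit 5.50%), so an excess over chance was not detectable there (permutation p = 1).

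Most BRWD1 peaks in either list lay at neither mark, but most of those found in both replicates lay at H3K9Ac peaks of either replicate. Against the union of both replicates of each mark, 85.8% of BRWD1 replicate 1 and 85.3% of BRWD1 replicate 2 peaks overlapped neither mark, and 4.21% and 3.42% overlapped both. Among the 661 BRWD1 replicate 2 peaks that also overlapped replicate 1, 222 had both marks (33.6%, 30.1 to 37.3), 244 had H3K9Ac alone (36.9%), 34 had H3S10pK14Ac alone (5.14%) and 161 had neither (24.4%, 21.2 to 27.8). Of the BRWD1 replicate 1 peaks at both marks 95.9% were found again in replicate 2, against 3.37% of those at neither; the shares of replicate 2 peaks found in replicate 1 were 65.1% and 1.89%. The peaks at both marks include those in the 147 regions with a peak in all 5 larger lists, which hold both BRWD1 lists and both marks by definition. Outside these regions lay 143 of the 299 BRWD1 replicate 1 peaks with H3S10pK14Ac replicate 2, and 396 of the 546 of BRWD1 replicate 2. The shares found again, and the scores that follow, are not given without these regions. Peaks at both marks also scored higher. Their mean score percentile within the list was 90.7 against 45.2 for peaks at neither mark in replicate 1, and 88.7 against 46.7 in replicate 2. Peaks at H3K9Ac alone (74.5 and 63.0) and at H3S10pK14Ac alone (68.3 and 63.8) lay between. Each class differed from the peaks at neither mark in both lists (two-sided permutation test of ranks, p = 1e-05, the smallest the resamples can give; the same value after adjustment over 6 tests).

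**Figure D3:**
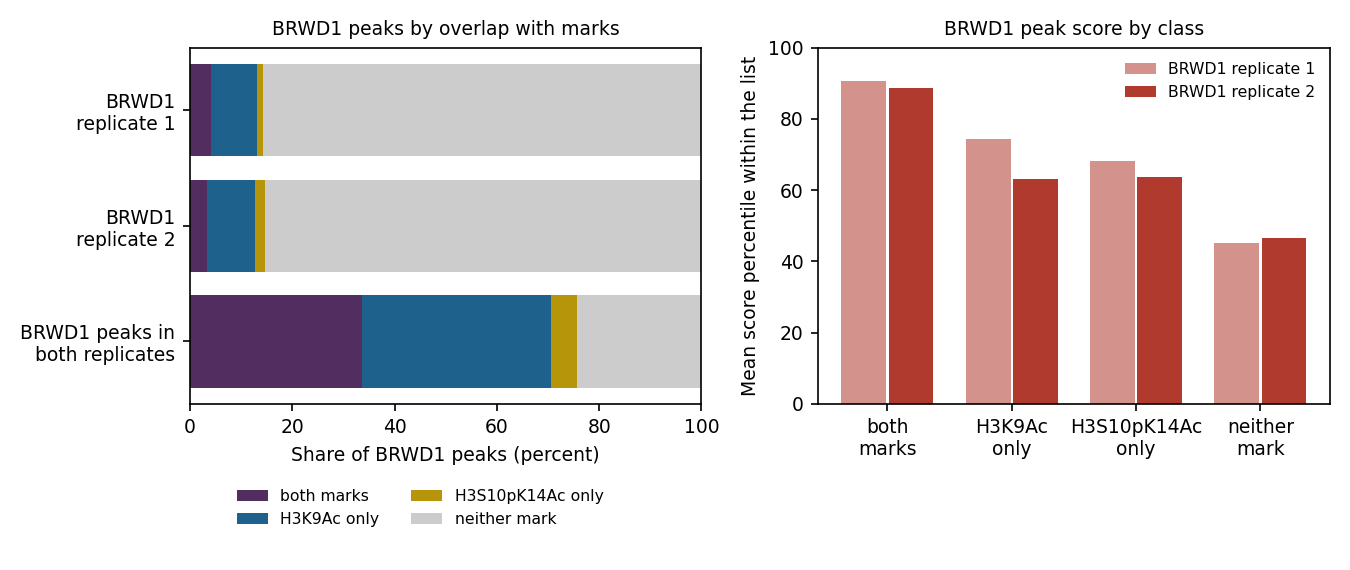
Left, share of BRWD1 peaks (horizontal axis, percent) that overlapped both marks, H3K9Ac alone, H3S10pK14Ac alone or neither, in each replicate list and among replicate 2 peaks that also overlapped replicate 1; right, mean score percentile within each BRWD1 list by class. Peaks at neither mark made up 85.8% and 85.3% of the lists but 24.4% of the peaks found in both.

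At Igk, BRWD1 and both marks converged on a few kilobases of chromosome 6 (mm9), between 70668924 and 70676977, which gave some of the strongest peaks in the genome for each antibody. The highest-scored peak of BRWD1 replicate 1 lay at chromosome 6, 70675735 to 70676851 (score 214.6). H3K9Ac replicate 1 had its highest-scored and widest peak over the same place, from 70668924 to 70676977 (8054 bp, score 676.0), and H3S10pK14Ac replicate 1 had its highest-scored peak at 70675737 to 70676848 (score 85.8). The ends of these BRWD1 and H3S10pK14Ac peaks differed by at most 3 bp, against a median of 21.5 bp among the 36 other peaks the lists shared. In the replicate 2 lists, the best Igk peaks were BRWD1 at 70672399 to 70674204 (score 72.0, rank 8 of 9966), H3K9Ac at 70672379 to 70676748 (score 75.1, rank 8 of 16453) and H3S10pK14Ac at 70672386 to 70673746 (score 70.6, rank 2 of 10638). BRWD1 replicate 2 had a further peak at 70675648 to 70676090 (score 48.3, rank 17), which overlapped the replicate 1 peak. In the Igk window, taken as 67 to 71 Mb, the BRWD1 peaks of both replicates met in 2 regions. The first, 70675648 to 70676851, had a peak in all 6 lists. The second, 67780956 to 67781209, had peaks in 5 lists, with scores of 21.9 and 22.4 for BRWD1, 15.5 and 9.89 for H3K9Ac, and 8.06 for H3S10pK14Ac replicate 2. No mm9 gene annotation was used here, so these positions were not assigned to gene segments, exons or enhancers.

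**Figure D4:**
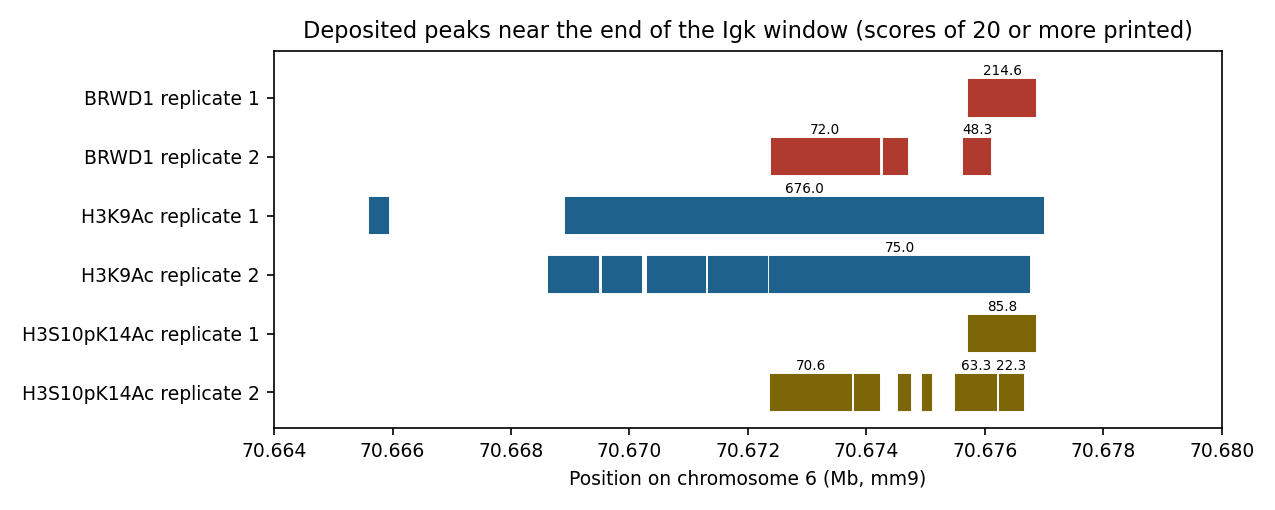
Peaks of the 6 lists near the end of the Igk window (horizontal axis, position on chromosome 6 in Mb, mm9), drawn to scale, with scores of 20 or more printed above them. Each list has a peak overlapping 70675735 to 70676851, and the BRWD1 and H3S10pK14Ac peaks at 70672386 to 70674204 are in replicate 2 alone.

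The number of BRWD1 peaks across the Igk window was not unusual. Each BRWD1 list had 12 peaks there; 75.5% of the other 4 Mb windows had fewer in replicate 1 and 27.5% in replicate 2. The window held 18 and 34 H3K9Ac peaks and 1 and 19 H3S10pK14Ac peaks, and 61.3 to 87.4% of other windows had fewer. The 87.4% belongs to H3S10pK14Ac replicate 1 and stands for windows with no peak. The best score in the window was higher than that in 98.9 to 100% of other windows in all 6 lists. The count of 12 depended on the weaker peaks, since at scores of 10 or more a mean of 2.5 BRWD1 peaks per list was left.

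The heavy chain locus, Igh, had a region with peaks of all 6 lists too, at lower BRWD1 and H3S10pK14Ac scores within each list than the Igk region. This region, chromosome 12 from 114662424 to 114668067, held the best peak of each list in the 4 Mb Igh window. H3K9Ac peaks there ranked 2 (114663347 to 114668015, score 170.9) and 1 (114662424 to 114665672, score 106.6) in replicates 1 and 2. The BRWD1 peaks ranked 433 (114664507 to 114664766, score 11.1) and 80 (114662719 to 114664386, score 23.3), and the H3S10pK14Ac peaks ranked 22 of 103 (114666041 to 114666651, score 7.70) and 608 of 10638 (score 7.92). The best score in the Igh window exceeded that of 55.7% and 90.7% of other windows for BRWD1, and of 97.1% and 44.3% for H3S10pK14Ac. The 97.1% belongs to H3S10pK14Ac replicate 1, in which 87.4% of other windows held no peak. BRWD1 peaks covered 1883 and 6009 bp of the Igh window, more than in 99.5% and 97.4% of other windows, and 1904 and 4710 bp of the Igk window, more than in 99.6% and 85.9%. The lambda light chain (Igl) window, chromosome 16 from 19 to 20 Mb, held 11 and 24 H3K9Ac peaks, more than 89.5% and 98.0% of other 1 Mb windows, with 2 BRWD1 peaks in each list that scored at most 5.39 and 5.48. In the T cell receptor windows BRWD1 peaks numbered 2 and 10 at Tcrb, 4 and 4 at Tcra/Tcrd, and 3 and 3 at Tcrg, and 10.6 to 70.6% of other windows of the same width had fewer. The best of them, at Tcra/Tcrd in replicate 2 (chromosome 14, 54464559 to 54464808), scored 17.4 and ranked 133. The best BRWD1 replicate 1 peak of that window (54464654 to 54464720, score 6.91, rank 800) lay inside it. Differences between the loci were not tested.

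The 10 BRWD1 regions with the best mean rank in both replicates all carried both marks in at least a single replicate, and 7 had a peak in all 6 lists. All 10, the 2 Igk regions and the Igh region were among the 147 regions of the genome with a peak in all 5 larger lists. The first lay on chromosome 4, 124546333 to 124546830, with BRWD1 scores of 102.4 and 150.5, H3K9Ac scores of 120.3 and 63.4, and H3S10pK14Ac scores of 11.3 and 70.6. A pair lay close together on chromosome 17, at 39984171 to 39985240 (BRWD1 scores 93.9 and 94.1) and 39983590 to 39983980 (59.6 and 54.8). The rest were on chromosome 13 (92813776 to 92814082 and 23488828 to 23489088), chromosome 12 (47959158 to 47959437), chromosome 6 (the Igk region above), chromosome 10 (62892137 to 62892403) and chromosome 2 (149350229 to 149350498 and 98506309 to 98507551). The 3 without an H3S10pK14Ac replicate 1 peak were the chromosome 17 pair and chromosome 2 at 98506309 to 98507551. Of the 10 highest-scored H3S10pK14Ac replicate 1 peaks, 9 lay at BRWD1 peaks of both replicates. The exception was chromosome 15, 74915957 to 74916034 (score 15.2), which overlapped only a BRWD1 replicate 1 peak of score 6.83.

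The listed BRWD1 peaks, most of them weak and found in a single replicate, were spread more evenly over the genome than H3K9Ac peaks. The variance of peaks per 1 Mb window was 1.67 and 1.72 times the mean for BRWD1 and 6.43 and 5.99 times the mean for H3K9Ac. For H3S10pK14Ac replicate 2 it was 2.22 times the mean, so the evenness was not particular to BRWD1. The 1.66 of H3S10pK14Ac replicate 1 rests on 103 peaks, a mean of 0.0389 per window, and cannot be compared with the longer lists. Only 7.72% and 3.96% of BRWD1 peaks scored 10 or more, and whether these were spread as evenly was not tested. Chromosome 11 had 1.77 and 1.58 times the genome's H3K9Ac peak density, against 1.03 and 1.12 times for BRWD1. Chromosome X was low for each antibody, at 0.607 and 0.448 times the genome's density for BRWD1, 0.281 and 0.262 for H3K9Ac, and 0.467 and 0.402 for H3S10pK14Ac. The densest BRWD1 window was chromosome 9 from 3 to 4 Mb, with 48 and 34 peaks against genome means of 2.19 and 3.76 per window. It also held 10 and 27 H3K9Ac peaks and 0 and 25 H3S10pK14Ac peaks, and it was the densest window of H3S10pK14Ac replicate 2 too. Several of the 147 regions with a peak in all 5 larger lists lay there, so high signal in every library stays open for this window. Repeats and mappability were not examined for it or for the best BRWD1 regions named above. The next densest windows, on chromosome 13 (1 Mb from 113 Mb), chromosome 10 (1 Mb ending at 119 Mb), chromosome 17 (50 to 51 Mb) and chromosome 18 (55 to 56 Mb), held 6 to 7 and 11 to 13 BRWD1 peaks.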

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

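The tests of regions called with every antibody in the short list, of H3S10pK14Ac replicate 1 without shared regions, of differently numbered lists, of top-scored lists of equal length, and of peak ends on chromosome 6 were chosen after the results were seen; the other tests of explanations were set out before their results.

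Peaks on the mitochondrial chromosome lay outside the comparisons above and appeared in all replicate 2 lists, with 16 for BRWD1, 15 for H3K9Ac and 4 for H3S10pK14Ac. In the replicate 1 lists BRWD1 had 2, and H3K9Ac and H3S10pK14Ac had 0. The best of these peaks scored 39.2 for BRWD1 replicate 2 and 38.2 for H3K9Ac replicate 2.

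The H3S10pK14Ac lists differed in length, with 103 peaks in replicate 1 and 10638 in replicate 2. A list made mainly of regions called with every antibody is argued against, since 30.1% of the 103 peaks (22.1 to 39.5) overlapped all 4 BRWD1 and H3K9Ac lists and 64 overlapped no other list. A lower depth or enrichment of the replicate 1 library cannot be told apart from other causes of a short list: the 32 replicate 2 peaks it overlapped had a median score percentile of 99.5, but the 103 top-scored replicate 1 peaks of BRWD1 and H3K9Ac gave 99.3 and 96.6 in the same way. Read counts, which would decide, are not used here. No biological explanation was tested, since the replicates belong to the same group.

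Peaks of different antibodies overlapped above chance in every directed pair of lists, and 147 regions had a peak in all 5 larger lists. These 147 regions cannot be the whole cause genome-wide for BRWD1 with either mark. Without those regions 7.07% of BRWD1 peaks still had H3K9Ac (highest of the shifted lists 0.356%) and 3.28% had H3S10pK14Ac replicate 2 (0.252%). Likewise, 6.85% of H3S10pK14Ac replicate 1 peaks had BRWD1 (2.05%). Of the 24 directed pairs of different antibodies, 22 stayed above the highest shift. The exceptions were H3S10pK14Ac replicate 1 and H3K9Ac replicate 2 in either direction, which kept 2 of 32 overlaps. The shares were 2.74% (highest shift 2.74%, permutation p = 0.01) and 0.0123% (0.0184%, permutation p = 0.008). For H3S10pK14Ac replicate 1 most of the overlap did lie in those regions, since 7 of its 37 peaks with BRWD1 replicate 1 and 3 of its 33 with BRWD1 replicate 2 were outside them; the same regions hold the 10 best BRWD1 regions and the named Igk and Igh regions, for which high signal in every library therefore stays open. A technical source tied to the replicate number cannot be the whole cause for BRWD1 and H3K9Ac. The lower of their differently numbered pairs of lists was 29.0 times chance. A contribution of such a source stays open. Same-numbered lists overlapped 1.34 (BRWD1 and H3K9Ac) to 1.62 times (BRWD1 and H3S10pK14Ac) as far above chance as differently numbered ones. The 1.62 includes a fold of 1088 (BRWD1 and H3S10pK14Ac, both replicate 1), whose chance of 0.000585% was too low for a precise fold. A shared input library, or regions of high signal called in fewer than 5 lists, could still account for the overlap outside the 147 regions. Neither was tested. Binding of BRWD1 at chromatin with both marks, the subject of the design, stays open as a hypothesis.

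At Igk, the BRWD1 and H3S10pK14Ac peaks of replicate 1 at 70675735 to 70676851 of chromosome 6 had nearly the same ends. They differed by at most 3 bp, against a median of 21.5 bp (quartiles 13.8 and 40.5) among the 36 other peaks these lists shared, of which 0 were as close. This is consistent with a DNA fragment with fixed ends in both libraries, a hypothesis found and tested on the same data. The corresponding replicate 2 peaks started 142 bp and ended 100 bp apart, and both marks and BRWD1 had peaks there in replicate 2. Binding at this site therefore stays open as well, and read coverage would be needed to tell these apart.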

How the results depend on the processing

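The alternatives with scores of 10 or more, without regions that had a peak in all 5 larger lists, and without the Igk window were chosen after the data were seen. Of 139 alternative values, 131 kept their direction and their side of the threshold or, for the Igk window count, stayed the same. Of the others, 1 weakened and 7, all Igk window counts, moved. There were 0 reversals, which were not defined for the Igk window count. These calls do not cover the size of a value. The shares ranged from 7.07 to 34.5% for BRWD1 peaks with H3K9Ac, 0.484 to 13.9% for BRWD1 peaks with H3S10pK14Ac, 3.97 to 7.97% for H3K9Ac peaks with BRWD1, 3.94 to 100% for H3S10pK14Ac peaks with BRWD1 and 0.280 to 4.59% for H3K9Ac peaks with H3S10pK14Ac. The overlaps between antibodies exceeded chance under each of 17 alternatives per comparison. They were 9.57 to 430 times chance for BRWD1 peaks with H3K9Ac and 7.12 to 6200 times for BRWD1 peaks with H3S10pK14Ac. The 6200 and the 100% above came from peaks in both replicates, where H3S10pK14Ac had few (31 of its 103 replicate 1 peaks). Chance for the 6200 was 0.000756% over 200 shifts, too low for a precise fold. The odds ratio of 78.6 ranged from 10.2 (without the 1% highest-scored peaks) to 1361 (peaks in both replicates). It was 59.1 within deciles of H3K9Ac peak width and 48.1 within deciles of score. Without the regions that had a peak in all 5 larger lists it was 13.9, and the largest p of its combinations rose to 0.0963; that setting removes doubly marked peaks with BRWD1 by construction. Leaving out libraries, it lay between 21.4 (without H3S10pK14Ac replicate 1) and 289 (without H3S10pK14Ac replicate 2).

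The mean of 12 BRWD1 peaks in the Igk window was 7 for scores above the list's median, 10 without the 1% highest scores, 10.5 with equal numbers of top-scored peaks, 22 in the union of replicates, 2 in both replicates, 2.5 at scores of 10 or more and 9 without the regions in all 5 larger lists. Each of these settings except the union keeps fewer peaks by construction. The replicate numbers are not stated to mark a shared day or batch, and a block on them, using same-numbered lists alone, changed no call. Under this block the shares were 10.6% for BRWD1 peaks with H3K9Ac, 3.06% for BRWD1 peaks with H3S10pK14Ac and 6.06% for H3K9Ac peaks with BRWD1. Further values under the block were 20.6% for H3S10pK14Ac peaks with BRWD1, 2.43% for H3K9Ac peaks with H3S10pK14Ac and 58.2 for the odds ratio. Same-numbered lists overlapped 1.34 (BRWD1 and H3K9Ac) to 1.62 times (BRWD1 and H3S10pK14Ac) as far above chance as differently numbered ones. The 1.62 is imprecise, since it includes the fold of 1088 of BRWD1 and H3S10pK14Ac replicate 1, at a chance of 0.000585%. A score of 100 or more, planned for another score scale, and promoter distances were not run, and overlap settings do not apply to the window count. Unknown read depth limits any statement on peaks absent from a list.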

Other observations

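Peaks of H3S10pK14Ac replicate 1 fell into separate kinds: 29 of the 103 overlapped all 5 other lists and 64 overlapped none, with 10 between. Of these 103 peaks, 16 lay on chromosome 8, at 3.15 times the list's density over all chromosomes, and 8 of them were between 19 and 20 Mb. The densest windows of H3K9Ac were chromosome 3 from 95 to 96 Mb in replicate 1 and chromosome 7 from 52 to 53 Mb in replicate 2, with 37 peaks each. Across 2651 windows of 1 Mb, Spearman's rho of peak numbers was 0.84 between the H3K9Ac replicates and 0.299 between the BRWD1 replicates. The H3K9Ac lists (replicates 1 and 2) had a rho of 0.494 and 0.539 with BRWD1 replicate 2, and of 0.252 and 0.268 with BRWD1 replicate 1. These are correlations across windows, which are not independent replicates, and they were not tested.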
